A study of Mus musculus with 8 samples.

How the data were processed

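The series profiled RNA of mouse bone marrow mesenchymal stem cells by high-throughput sequencing. Per the labels, 8 samples cover 4 polycaprolactone (PCL) scaffolds at day 3 and day 7 of osteogenic culture, with 1 sample per scaffold and day. The scaffolds were PCL alone, PCL with SS31, PCL with E7, and PCL with both peptides. The labels' protocols describe medium conditioned by the scaffolds, TRIzol extraction of RNA and a SMARTER library kit. They mention RNA samples in triplicate. The build mm10 is named in the submitters' processing notes. The aligner, the counting program and the annotation release are not given in the sources used here.

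The authors deposited a table of all genes and a table of mitochondrial genes. Per the file headers, each gives a read count and an FPKM value (fragments scaled to transcript length and library size) for 4 libraries, together with gene coordinates, gene length, symbol, Gene Ontology (GO) terms and a description for each gene. The 4 libraries are named PCL, PCL-R, PCL-B and PCL-R-B. No name carries a day, while each scaffold has 2 samples, and no label says what R and B stand for. The tables hold 4 libraries against 8 samples. None of the 16 columns of per-library values, 8 in each table, was therefore matched to a sample, and none was used. Their headers and values were inspected to record what the columns hold, and no result rests on them. Comparisons between scaffolds, between peptides and between days, and the sequencing depth of each sample, were not analysed here.

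The gene annotation columns and the membership of the mitochondria table belong to no single sample and were analysed. Of the 21935 gene identifiers in the table of all genes, 21816 (99.5%) matched the GENCODE M21 annotation of mouse GRCm38. Of these, 21616 (99.1%) had the same chromosome, start, end and strand there. Coordinates are 1-based, as deposited, on mm10. The table of all genes had 1 line emptied before it was used here.

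For each gene, membership of the mitochondria table was compared with the text of the deposited description and with the deposited GO annotation. Gene lists had been fixed before the data were examined, 33 in all, of which 11 describe mitochondrial functions. They were fixed for tests of expression and were used here for membership only. Counts of held genes cover every gene in the tables, so they carry no sampling or replicate error and are given without intervals. Fisher's exact tests of the lists were also run and are not reported, because membership followed the wording of the gene descriptions for every gene, which fixes the outcome for lists whose genes share a description. The membership counts, the families grouped by symbol and the alternatives were chosen after the tables were seen. Genes to be named had also been fixed beforehand, 18 in number, with further names taken from the lists. Other genes named below, from the symbol families and the exceptions to a rule, were chosen after the tables were seen. Analyses used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.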

Results

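The study used mouse bone marrow mesenchymal stem cells, the stromal progenitors that give rise to osteoblasts, under osteogenic conditions. The samples are labelled by PCL scaffold, and the labels' protocols describe medium in which scaffolds had been soaked. PCL is a degradable polyester used for bone scaffolds. SS31 is a short peptide that targets mitochondria, and E7 is a peptide with affinity for mesenchymal stem cells. Per the labels, the 8 samples fall into 8 groups of 1, namely PCL, PCL with SS31, PCL with E7 and PCL with both peptides, each at day 3 and day 7. The layout poses 3 questions, namely how each peptide changed the transcriptome relative to PCL alone, whether both together differed from either alone, and how day 7 differed from day 3. The 4 libraries in the deposited tables were not matched to single samples, so no expression value, fold change or depth is reported for these questions. The data below describe which genes the deposited mitochondria table covers, out of those in the deposited table of all genes.

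The mitochondria table held all 13 protein-coding genes of the mitochondrial genome. It also held nearly all genes with Mrpl or Mrps symbols and most of the listed ATP synthase genes. No gene from the fixed lists of nuclear genes for respiratory complexes I to IV was held. The mitochondria table contained 299 genes, 1.36% of the 21935 genes in the table of all genes. Of the 299 genes, 286 are nuclear and 13 lie on the mitochondrial chromosome. The mitochondrial genes include mt-Nd1 (MT, 2751 to 3707, plus strand), a complex I subunit, mt-Co1 (MT, 5328 to 6872, plus strand), a complex IV subunit, and mt-Nd6 (MT, 13552 to 14070, minus strand), a complex I subunit.

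Membership followed the wording of the gene descriptions without exception. The character string "mitochondria", which also occurs in "mitochondrial" and "mitochondrially", stood in the deposited description of 299 genes, and all 299 were in the mitochondria table. No gene without the string was in it. The shorter stem "mitochond" matched 302 genes. The 3 that were left out were Aifm1 (chromosome X, 48474944 to 48513563), Aifm2 (chromosome 10, 61715263 to 61739260) and Aifm3 (chromosome 16, 17489611 to 17507485), members of the apoptosis-inducing factor family whose descriptions read "mitochondrion-associated".

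The table covered a minor part of the genes annotated to mitochondria. Of 1735 genes with the GO term mitochondrion, 289 (16.7%) were held and 1446 were not. Among 413 genes with the term for the inner membrane, 105 (25.4%) were held. The corresponding numbers were 26 of 171 (15.2%) for the outer membrane and 43 of 223 (19.3%) for the matrix. In the other direction, 10 of the 299 genes lacked the GO term mitochondrion, among them Mtus1, Cluh, Tmem243, Cars2, Mto1 and Ptpmt1. The 10 include a second identifier of Atp5o, whose other identifier carries the term. Totals such as 299 count gene identifiers, while the numbers of listed genes held count symbols. The term was matched exactly, without narrower terms.

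Most genes with the symbols of mitochondrial ribosomal proteins, membrane translocases and mitochondrial aminoacyl-tRNA synthetases were held. Genes of mitochondrial translation or import with other symbols were not counted in these families. The families were matched by symbol, which does not show that every member belongs to the complex named. All 49 genes with Mrpl symbols, named for the large subunit of the mitochondrial ribosome, were held. So were 28 of 29 with Mrps symbols, named for the small subunit, Mrps7 being the exception. The deposited description of Mrps7 is spelled "mitchondrial ribosomal protein S7" and so lacks the string, while the gene carries the GO term mitochondrion. All 15 genes with Timm symbols, named for inner membrane translocases, were held. So were all 10 with Tomm symbols, named for outer membrane translocases. Of 17 mitochondrial aminoacyl-tRNA synthetases, 15 were held, without Hars2 and Sars2. Of 7 genes of the calcium uniporter group, 6 were held, including the pore subunit Mcu, and Smdt1 was not. The 3 uncoupling protein genes with the symbols Ucp1, Ucp2 and Ucp3 were held, and no other symbols were searched for this group. The SLC25 carrier family, counted by symbol and whatever the membrane its members occupy, was divided, with 24 of 47 held, including the ADP/ATP carriers Slc25a4 and Slc25a5, and 23 left out, including the iron importers Slc25a37 and Slc25a28.

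Nuclear-encoded subunits of respiratory complexes I to IV were almost entirely outside the table, and most of the ATP synthase was in it. None of the 36 listed complex I genes and none of the 25 listed genes of complexes II to IV was held, against 16.7% of all genes with the GO term. These lists include Ndufs1, the largest complex I subunit, Sdha of succinate dehydrogenase, Uqcrc1 of complex III and Cox4i1 of complex IV. The list for complexes II to IV also counts cytochrome c (Cycs), an electron carrier and not a subunit. By symbol, 2 of 47 Nduf genes were held, Ndufa4 and Ndufa4l2, and 45 were not. The symbol match also took in Ndufaf assembly factors and Ndufb1-ps, and an Nduf symbol alone does not mark a complex I subunit. By the GO term for complex I, 1 of 41 nuclear genes was held. All 19 genes named for Cox subunits, Cox5b-ps among them, the 8 Uqcr genes and the 4 Sdh subunit genes were left out. By contrast, 14 of the 16 listed ATP synthase genes were held (87.5%), among them Atp5a1 and Atp5b of the catalytic head. Atp5pb and the inhibitor Atpif1 were left out. None of the listed complex I to IV genes had the string "mitochondria" in its description, and all 14 held ATP synthase genes did. String and membership coincided for every gene, so each share here equals the share of descriptions with the string. The list of mitochondrial ribosomal proteins was held in 29 of 30 and the list of mitochondrial-genome proteins in 13 of 13.

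**Figure D1:**
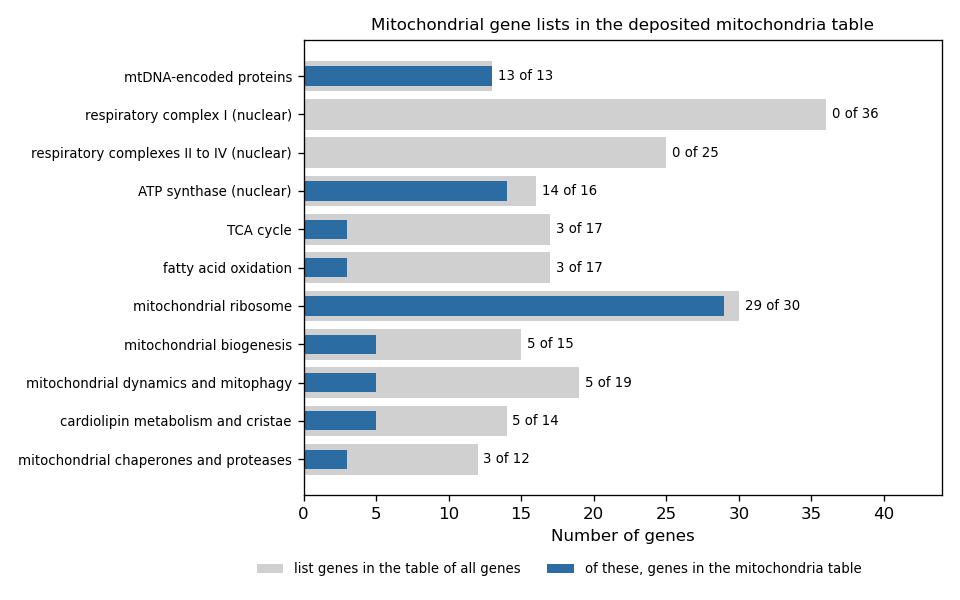
Horizontal bars give the number of genes in each of 11 mitochondrial gene lists that occur in the table of all genes (grey) and the number of those that the deposited mitochondria table holds (blue). The mitochondrial ribosome list stands at 29 of 30 and the nuclear complex I list at 0 of 36.

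Regulators of mitochondrial number, shape and turnover were held in part. Of 15 biogenesis genes, 5 were held. They were Tfam (chromosome 10, 71225464 to 71238280), Tfb1m and Tfb2m, all described as transcription factors, the RNA polymerase Polrmt, and the protease Lonp1. The coactivator Ppargc1a (chromosome 5, 51454250 to 51567726), the transcription factor Nrf1 and the DNA polymerase Polg were not. Of 19 dynamics and mitophagy genes, 5 were held, namely the fusion GTPase Opa1 (chromosome 16, 29579334 to 29654884), Fis1, Mff, Mief1 and Mief2. The mitofusins Mfn1 and Mfn2, the fission GTPase Dnm1l and the mitophagy genes Pink1, Bnip3 and Fundc1 were left out. Of 14 cardiolipin and cristae genes in the table of all genes, 5 were held, including Immt and Ptpmt1, while the cardiolipin synthase Crls1 was not. Counting only genes with the GO term, the shares held were 29.4% for dynamics and mitophagy and 33.3% for cardiolipin and cristae.

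Genes of central metabolism and protein quality control were held at shares of 17.6% for the tricarboxylic acid cycle, 17.6% for fatty acid oxidation and 25.0% for chaperones and proteases, beside 16.7% of all genes with the GO term mitochondrion. Of 17 tricarboxylic acid cycle genes, 3 were held, including Idh2 and Mdh2, and citrate synthase Cs was not. Of 17 fatty acid oxidation genes, 3 were held, Acaa2, Echs1 and Slc25a20, and the carnitine palmitoyltransferases Cpt1a and Cpt2 were not. Of 12 mitochondrial chaperones and proteases, 3 were held, Clpp, Clpx and Lonp1, and the chaperones Hspd1 and Hspa9 were not. Of the 22 lists for other functions and cell types, 20 had no gene in the table, osteoblast differentiation among them. The other 2 had 1 gene each, Sod2 (chromosome 17, 13006846 to 13040063) of 26 antioxidant genes and Shmt2 of 19 stress-response genes. Among the 15 antioxidant genes that carry the GO term mitochondrion, 1 was held (6.7%). Prdx3, Txn2 and Txnrd2 were among the antioxidant genes left out. Of the 18 genes fixed for naming, 3 were in the mitochondria table, Sod2, Tfam and Opa1.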

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

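None of the alternatives planned for the expression comparisons was run, because no per-library column was matched to a sample, and every alternative given here was chosen after the tables were seen. The share of GO mitochondrion genes held, 16.7%, was 25.4% for inner membrane genes, 19.3% for matrix genes, 15.2% for outer membrane genes and 16.7% with 1 identifier per symbol. The number of genes matched by description, 299, was 302 with the stem "mitochond" and 296 with "mitochondrial". No depth enters these values.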

Other observations

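Both comparisons in this part were chosen after the result was seen. No gene on the fixed nuclear lists for respiratory complexes I to IV was in the mitochondria table, which does hold Ndufa4 and Ndufa4l2. This absence may come from the way descriptions are worded, if the table was made by searching descriptions for the string "mitochondria". String and membership disagreed for 0 of 21935 genes, but that agreement is what raised the explanation, so it is not an independent test and the explanation stays open as a hypothesis. Selection by the GO term mitochondrion alone is argued against by 1446 genes that carry the term and were left out. Descriptions of Mfn2 ("mitofusin 2") and Dnm1l ("dynamin 1-like") lack the string, although both genes carry the GO term. The misspelled description of Mrps7 ("mitchondrial") also lacks the string, and Mrps7 was the only gene with an Mrpl or Mrps symbol that was left out. No biological explanation was tested, and how the authors made the table is not stated in the sources used here.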
